A study of Homo sapiens with 132 samples.

How the data were processed

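MicroRNA levels were measured by TaqMan real-time PCR in 132 human bladder tumour samples, 80 labelled conventional urothelial carcinoma and 52 labelled sarcomatoid carcinoma. Each sample was run on 1 array card of 384 wells with assays for 377 human microRNAs and 7 control wells, 4 of them U6 and 1 each RNU44, RNU48 and the plant microRNA ath-miR159a. Per the labels, total RNA was extracted with MasterPure Complete and the label protocol was Human Pool A. Groups were taken from the source label of each sample. The labels do not state that each sample came from a separate patient, so the p-values measure the spread between samples.

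The authors deposited 2 tables that were used. The first holds Ct, the PCR cycle at which a well crossed the detection threshold, where a lower value means more RNA and 40 marks a well that did not amplify. Readings of 40 made up 22.8% of all wells and readings from 35 to under 40 made up 3.78%. The second deposited table holds delta-Ct, a log2 scale if each cycle is taken as 1 doubling. The labels do not name the reference, but the deposited Ct minus the deposited delta-Ct was 1 constant per sample and equalled the RNU48 Ct of that sample, with a largest difference of 3.6e-15 cycles. The deposited table of fold changes was not used, since its 131 columns have names that match no sample's labels. The instrument software, threshold and baseline settings are not given in the sources used here. No 2 samples held the same values, as the smallest largest-assay difference between 2 samples was 7.92 cycles.

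The value analysed was minus delta-Ct. Readings at or over Ct 35 were first set to 35, and the RNU48 Ct of the sample was then subtracted. Tested were the 299 human assays with Ct under 35 in at least 50% of the samples of either group. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjusted p under 0.05). Lists of microRNAs were tested with limma's camera at a preset correlation of 0.01 for lists with at least 3 tested members, and again with an estimated correlation. The 20 lists, the tests, the first series of other settings and the rule for naming assays were fixed before the data were examined. Named are all miR-200 family assays, the 12 largest higher and the 12 largest lower called assays that were detected in at least 50% of the group in which they were higher, up to 4 assays of each other list by p, and the controls. Assays named outside this rule were chosen after their values were seen.

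Detection (Ct under 35) was compared with Fisher's exact test per assay over all 377 human assays, with exact binomial 95% intervals. Single measures were compared with 2-sided permutation tests of 100000 resamples, for which 1e-05 is the smallest p that can be given. Where a group held fewer than 10 samples, as in set 1, all permutations were counted and the test is called exact. A miR-200 to mesenchymal index was computed per sample as the mean Ct of the fibroblast and mesenchymal list minus the mean Ct of the miR-200 family. It needs no reference gene. No sequencing depth applies to these data, and the amount of RNA per well was read from the mean Ct of the 77 assays that were under 35 in every sample.

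After the main results had been seen, 3 sets of samples were found by assays with displaced Ct ranges. Set 1 has miR-299-5p under Ct 24 and holds 9 conventional and 20 sarcomatoid samples. Set 2, of the remainder, has miR-888 under Ct 24 and holds 20 conventional samples. Set 3 holds the other 51 conventional and 32 sarcomatoid samples. The limit of 24 and the sets were chosen after seeing the data, and the labels name no card lot or run. Set 2 holds conventional samples alone, so no difference can be given within it. Every conventional sample of sets 1 and 2 has a title number under 45, and every conventional sample of set 3 has a title number of 45 or above. Sarcomatoid replicates, which are numbered in title order, are all of set 1 from 1 to 20 and all of set 3 from 21 to 52. Fits with set as a covariate, within set 1 and within set 3 were added, as were fits with other references plus set, with mean Ct as a covariate, with samples matched on mean Ct within 0.5 cycles (36 pairs), with assays detected in every sample, and without conventional replicate 16.

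The limma fit was tested on simulated data for this comparison, with 299 assays, 60 of them changed, in 20 runs. Without a floor, 86.8% of assays changed by 2 log2 units were called, 28.8% of those changed by 1 and 3.25% of those changed by 0.5, against 0.314% of unchanged assays. With readings set to Ct 35 as in the main fit, 77.5%, 39.2% and 14.8% of changed assays were called, and 7.70% of unchanged ones. Of those 368 false calls, 364 were higher in sarcomatoid. The floor lies at a different delta-Ct in each group because RNU48 differs between them. The simulated noise was independent between assays and held no sample sets, unlike the real data, so these shares need not hold there. The main setting had been fixed and was kept, and counts that do not depend on the floor stand beside it. The first form of this simulation held the floor only and did not reach the recovery set for it, after which the form without a floor was added. Fisher's test, camera and the test of unequal differences between sets were also tested on simulated data.

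Alternatives covered 5 other references or scalings (the mean Ct of the 77 always detected assays, called the global mean; the median Ct of detected assays; U6; RNU44 with RNU48; quantile), the treatment of high readings, a Ct limit of 32, other detection filters, a permutation of ranks, limma with trend and robust settings or array weights, a covariate for the number of detected assays, a minimum log2 difference of 1, leaving out 14 samples with few detected assays, and each run of conventional titles alone. A fit on the deposited fold changes was planned and could not be run.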

Results

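Sarcomatoid carcinoma is a variant of bladder cancer with spindle-shaped, mesenchymal-like cells, and by its title the series addresses epithelial to mesenchymal transition in this variant. The data are Ct readings of 377 human microRNA assays in 80 conventional and 52 sarcomatoid tumours. A conventional sample had a median of 292 assays with Ct under 35 (range 113 to 373) and a sarcomatoid sample a median of 269 (range 147 to 320). The mean Ct of the 77 always detected assays was 19.9 ± 2.19 (SD, n = 80) in conventional and 22.5 ± 2.12 (SD, n = 52) in sarcomatoid samples, a difference of 2.62 cycles (permutation p = 1e-05). The difference was 1.93 cycles within set 1 (exact permutation p = 0.025) and 1.84 within set 3 (permutation p = 0.00021).

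The miR-200 family, which represses the transcription factors ZEB1 and ZEB2 and maintains epithelial identity, was lower in sarcomatoid tumours in all 5 of its assays. On the log2 scale, miR-429 (assay 001024) differed by -5.59 ± 0.65 (SE), miR-200b (002251) by -5.50 ± 0.62, miR-141 (000463) by -5.02 ± 0.62, miR-200a (000502) by -4.87 ± 0.58 and miR-200c (002300) by -4.83 ± 0.58. In fold terms miR-429 was 48.1-fold and miR-200c 28.5-fold lower, with limma adjusted p between 8.9e-13 and 7.6e-12. Between 44 and 48 of the 52 sarcomatoid samples lay below the conventional median, depending on the assay. In the gene table of assembly GRCh38.p14, MIR200A, MIR200B and MIR429 neighbour one another, as do MIR141 and MIR200C, and the assays of both clusters fell.

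The direction of these 5 assays was the same with every reference and in both sample sets. With set as a covariate the differences ran from -5.38 to -4.79, and within set 3 from -5.88 to -5.21. Within set 1, with 9 conventional samples, they ran from -3.78 to -3.11, and only miR-200c passed the limma threshold (adjusted p = 0.049). The family as a list was called (camera adjusted p = 5.4e-12, and adjusted p = 0.0072 with an estimated correlation), and all 5 members were also lower when adjusted over the list alone.

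**Figure D1:**
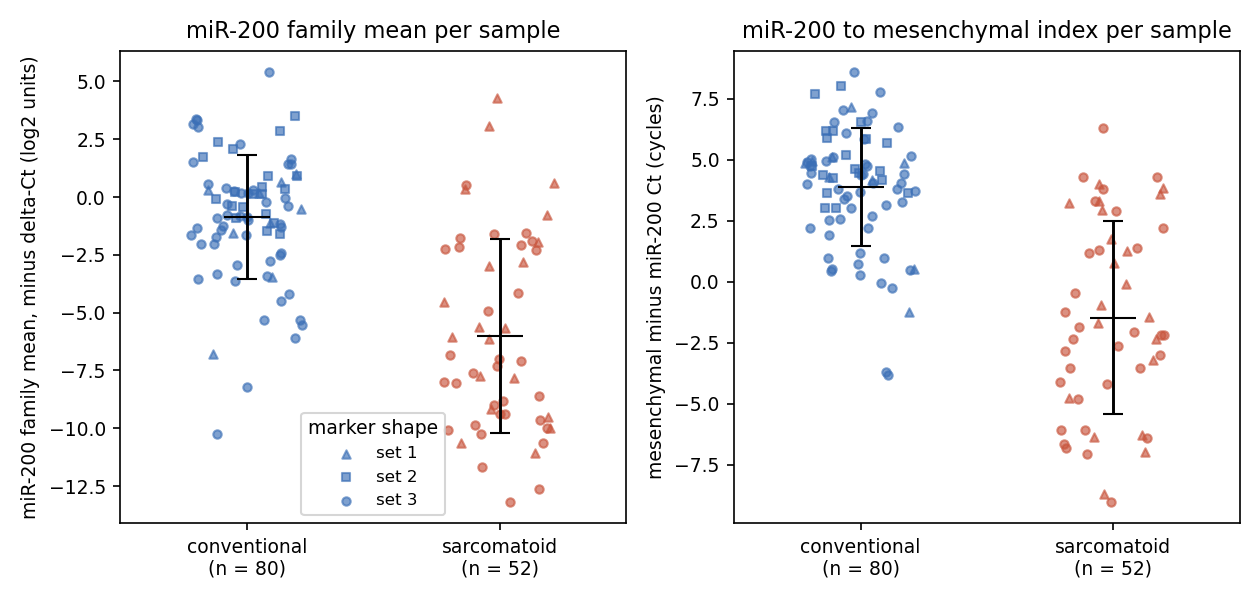
Left, mean of the 5 miR-200 family assays per sample as minus delta-Ct in log2 units; right, the miR-200 to mesenchymal index per sample in cycles. Each point is 1 sample, its shape gives the sample set, and bars give mean and SD of 80 conventional and 52 sarcomatoid samples; sarcomatoid samples average -1.47 in the index and conventional samples 3.88.

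The miR-200 to mesenchymal index, which sets the family against the 6 fibroblast and mesenchymal assays within each sample, was 3.88 ± 2.42 cycles (SD, n = 80) in conventional and -1.47 ± 3.97 (SD, n = 52) in sarcomatoid tumours. The difference was -5.35 cycles (permutation p = 1e-05). It was -4.76 within set 1 (exact permutation p = 0.0035) and -5.23 within set 3 (permutation p = 1e-05). A sarcomatoid sample had the lower index in 87.4% of all pairs of 1 sample from each group, and 15 sarcomatoid samples lay below the lowest conventional sample, at -3.82. The highest sarcomatoid sample reached 6.30, against 8.58 in conventional tumours.

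Sarcomatoid tumours also spread more widely in the family. The mean absolute deviation of the family mean from the group median was 3.48 log2 units in sarcomatoid and 1.96 in conventional samples (permutation p = 9e-05). Within set 1 the difference was 2.00 (exact permutation p = 0.058) and within set 3 it was 0.91 (permutation p = 0.063), so the larger spread did not pass the threshold within either set.

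Some other epithelial microRNAs were lower as well. Of the 7 tested on that list, 4 were lower and none higher. miR-203, which limits the proliferative capacity of skin stem cells, differed by -4.51 ± 0.66 (SE, limma adjusted p = 5.1e-09). miR-205, a microRNA of basal epithelia that also targets ZEB1 and ZEB2, differed by -3.87 ± 0.84 (adjusted p = 5.6e-05), but was below the conventional median in 33 of 52 sarcomatoid samples and differed by -0.71 within set 1 (adjusted p = 0.78). miR-182 differed by -2.06 and miR-183 by -1.82, while miR-96, encoded beside them, stood at 0.49 (adjusted p = 0.43). As a list they were called (camera adjusted p = 0.0022), and the call was lost with an estimated correlation (adjusted p = 0.34).

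Muscle microRNAs went in both directions. In the striated muscle list, miR-133a differed by -3.34 ± 0.54 (SE), miR-133b by -2.46 ± 0.57 and miR-1 by -2.36 ± 0.48, and miR-133a and miR-133b were called lower within set 1 and within set 3 separately. The fourth tested member, miR-499, was called higher at 1.24, although it was detected in 56 of 80 conventional and 14 of 52 sarcomatoid samples, and it was not called with set as a covariate (1.09, adjusted p = 0.065). The list was called lower (camera adjusted p = 0.010), and the call was lost with an estimated correlation (adjusted p = 0.34). In the smooth muscle list, miR-145 and miR-143, which are transcribed together, were lower by -1.74 ± 0.35 (SE) and -1.44 ± 0.38, while miR-99a and miR-100 were higher by 1.95 ± 0.35 and 1.85 ± 0.34. miR-143 stood at 0.23 within set 1 (adjusted p = 0.83), and with U6 as reference neither miR-99a nor miR-100 was called. That list was not called (camera adjusted p = 0.75).

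**Figure D2:**
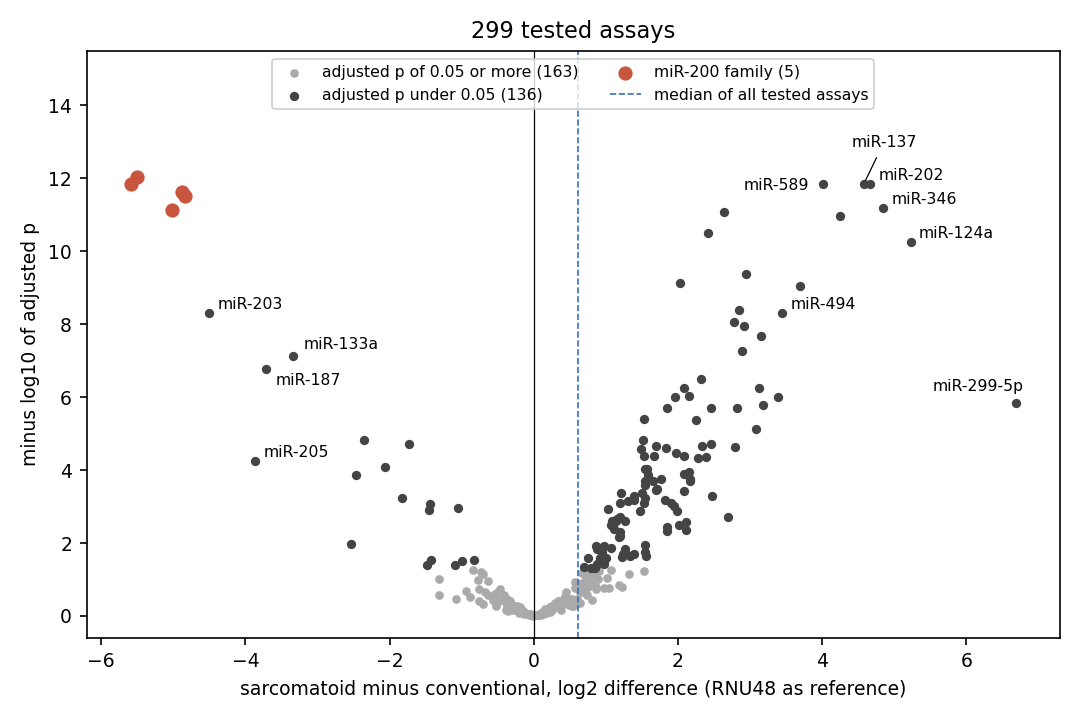
Each point is 1 of the 299 tested assays, with the log2 difference of sarcomatoid minus conventional samples on the horizontal axis and minus log10 of the limma adjusted p on the vertical axis. The 5 miR-200 family assays lie at the far left, and the median of all tested assays, the dashed line, is at 0.61.

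Across the card, 136 of the 299 tested assays differed between sarcomatoid and conventional tumours, 113 higher and 23 lower in sarcomatoid. The median difference of all tested assays was 0.61, so relative to it the miR-200 family lay between -6.20 and -5.44. The median and the balance of directions moved with the reference. The counts were 103 higher and 53 lower with the global mean (median 0.22), 58 and 95 with the median of detected assays (-0.32), 81 and 60 after quantile normalization (0.04), and 17 and 71 with U6 (-0.77). All 23 assays called lower were also called lower with the global mean and with U6, and 17 of the 113 called higher were also called higher with U6. With set as a covariate the counts were 109 and 30, within set 1 they were 74 and 4, and within set 3 they were 58 and 33. Called in both sets were 43 higher assays, where independent lists would share 14.1, and 4 lower ones, where they would share 0.47. The 4 were miR-200c, miR-133a, miR-133b and miR-187. Both sets share the reference and the detection limit, and RNU48 was later in sarcomatoid samples of each. More shared higher calls than 14.1 can arise from this alone.

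Among the higher assays, miR-124a and miR-137, both abundant in neurons, differed by 5.23 ± 0.68 (SE) and 4.58 ± 0.53. miR-202 differed by 4.66 ± 0.55, miR-346 by 4.84 ± 0.59, miR-672 by 4.24 ± 0.53 and miR-589 by 4.01 ± 0.46. From the imprinted DLK1-DIO3 cluster, miR-381 differed by 3.70 ± 0.52 and miR-494 by 3.45 ± 0.51. These 8 assays had limma adjusted p from 1.4e-12 to 5.1e-09, lay above the conventional median in 46 to 50 of the 52 sarcomatoid samples, and were higher within set 1 and within set 3. For miR-202 the difference was unequal, 8.77 in set 1 and 3.84 in set 3 (limma adjusted p = 0.025). The 8 were also higher with U6 as reference, with and without set as a covariate. The largest value of all, 6.68 for miR-299-5p, belongs to an assay that defines set 1, and with set as a covariate it was 1.47, and 0.63 within set 3 (adjusted p = 0.47). miR-627, at 3.17, miR-211, at 3.39, and miR-501, at 3.16, were not called with U6 and set together, and miR-627 was among the assays displaced in set 1.

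**Figure D3:**
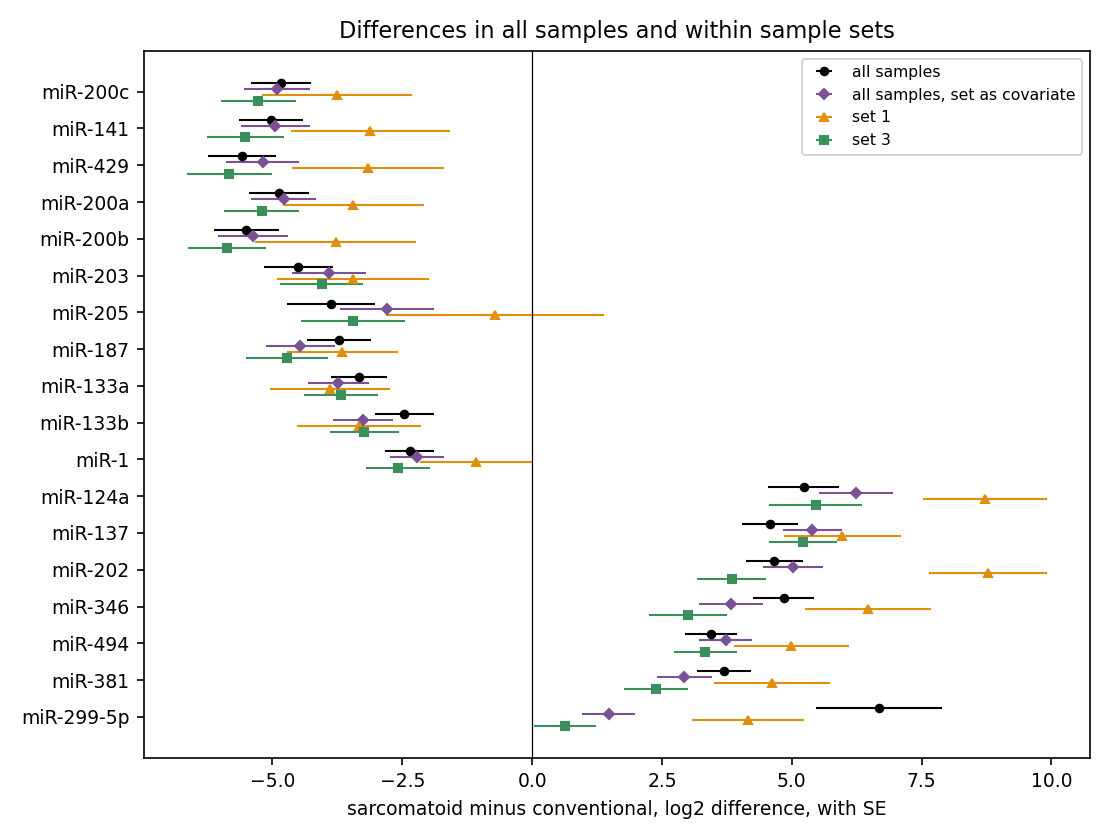
Log2 differences of sarcomatoid minus conventional samples with SE for 18 named assays, in all 132 samples, in all samples with set as a covariate, within set 1 (9 and 20 samples) and within set 3 (51 and 32 samples). The miR-200 family lies below 0 in each, and miR-299-5p falls from 6.68 to 0.63 within set 3.

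Among the lower assays, miR-187 differed by -3.72 ± 0.62 (SE, limma adjusted p = 1.6e-07), with -3.66 within set 1 and -4.72 within set 3. miR-518b, at -2.53 (adjusted p = 0.011), was among the assays displaced in set 2, and with set as a covariate it was -0.19 (adjusted p = 0.81). Readings set to the detection limit also weighed on the count of higher assays. Of the 113, 17 were detected in a smaller share of sarcomatoid samples by Fisher's test. Among the 77 assays never at the limit, 23 were higher and 5 lower. In simulated data with the same limit and independent noise, 7.70% of unchanged assays were called, 364 of those 368 calls being higher in sarcomatoid.

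Several lists fixed for known programmes had members called higher. Over the whole card 113 of 299 tested assays were called higher, a larger share than the 4 of 13 given below for miR-17 to miR-92. miR-210, the microRNA most closely tied to hypoxia, was higher by 1.53 ± 0.40 (SE, adjusted p = 0.00082) and was called in both sets. Of the p53-induced microRNAs, miR-34c and miR-34a were higher by 1.70 and 1.19, as was miR-215 at 1.23, which stood at 0.13 with set as a covariate. miR-221 and miR-21 rose by 1.55 and 0.88. In the clusters of miR-17 to miR-92 and their paralogues, 4 of 13 were higher over all assays, 7 with set as a covariate and 3 when adjusted over the list alone, among them miR-19a at 1.55 and miR-92a at 1.39. None of miR-210, miR-34a, miR-34c, miR-221, miR-21, miR-19a and miR-92a was called with U6 as reference. Of these lists none was called by camera, with adjusted p = 0.88 for the p53-induced list and 0.75 for the other 2 that could be tested. The list of miR-17 to miR-92 was called higher in matched samples (adjusted p = 0.0047, median 1.85) and with set and mean Ct as covariates (adjusted p = 0.0043), both at the preset correlation. With an estimated correlation it was not called in all samples (adjusted p = 0.98) or with set as a covariate (adjusted p = 0.97).

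Of the fibroblast, leukocyte, endothelial, red blood cell and neuronal lists, none was called in all samples with RNU48 and no covariate. Of 6 fibroblast and mesenchymal assays only miR-152 was higher, by 0.75 (adjusted p = 0.025), and none was when adjusted over the list alone. Of 8 leukocyte assays, miR-146b was higher and miR-342-3p and miR-150 were lower, and 4 were higher and 2 lower when adjusted over the list alone. Of 4 endothelial assays miR-139-5p was lower by -0.83. With the global mean the endothelial list stood at -0.93 ± 0.24 (SE), and camera at the preset correlation called it lower in matched samples (adjusted p = 0.028), with set and mean Ct (adjusted p = 0.041) and with set and the global mean (adjusted p = 0.047). It was not called with the global mean alone (adjusted p = 0.15), nor with an estimated correlation in all samples (adjusted p = 0.89) or with set as a covariate (adjusted p = 0.50). Of 3 red blood cell assays, miR-451 was higher by 2.08 and miR-486 by 1.98, and miR-486 lost the call with set as a covariate. miR-486-3p was called higher as well, but it was detected in 9 of 52 sarcomatoid and 47 of 80 conventional samples, turned to -1.01 with high readings as missing, and also lost the call with set as a covariate. The neuronal list had miR-124a and miR-129-3p higher, the latter detected in 12 of 52 sarcomatoid and 48 of 80 conventional samples and not called with set as a covariate (0.48, adjusted p = 0.51). With set as a covariate, 2 leukocyte assays were higher and 2 lower, and 2 endothelial assays were lower. Camera adjusted p was 0.75 for the fibroblast, leukocyte and neuronal lists, 0.22 for the endothelial list and 0.63 for the red blood cell list.

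Of 35 tested members of the DLK1-DIO3 cluster 9 were higher and 1, miR-431, was lower (camera adjusted p = 0.91), but with set as a covariate miR-431 was not called (-1.48, adjusted p = 0.065), and with set and the global mean it was (-1.89, adjusted p = 0.0078). Of 22 tested members of C19MC, a primate-specific cluster active in placenta, 3 were higher and 1 lower (camera adjusted p = 0.42), but 1 was higher and 2 lower with set as a covariate. The list was called lower within set 1 (adjusted p = 2.8e-05, median 0.15) and with set and mean Ct as covariates (adjusted p = 0.0043, median -1.27), both at the preset correlation. With an estimated correlation C19MC was not called in all samples (adjusted p = 0.98) or with set as a covariate (adjusted p = 0.97). In the let-7 family only let-7b was higher, by 1.52, and in the miR-15/16 family only miR-424, by 1.31 (camera adjusted p = 0.75 for both lists). With set as a covariate 2 of the miR-15/16 family were higher and 1 lower. No miR-29 family member was called (camera adjusted p = 0.91), and 1 was higher with set as a covariate. Of 2 tested embryonic stem cell assays miR-373 was higher, by 2.79, and of 2 from the X-linked cluster of miR-506 to miR-514, miR-509-5p was higher, by 2.15. Neither was called higher with U6 as reference, and miR-509-5p was not called within set 3 (1.55). An assay at the limit in every sample would read 3.00 higher in sarcomatoid, the RNU48 difference. With set as a covariate miR-373 was 1.96, and miR-372, the other embryonic assay, was called lower (-1.27). In all, 3 of 17 lists were called, and 1, the miR-200 family, with an estimated correlation. Camera compares a list with all other assays, so for the fibroblast, smooth muscle, DLK1-DIO3, leukocyte, let-7, miR-29, miR-15/16 and C19MC lists its direction was down although the median difference was above 0.

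Within groups, the relation of the miR-200 family to the mesenchymal list changed sign with the reference. With RNU48, Pearson's r was 0.44 in conventional samples (n = 80, permutation p = 4e-05, adjusted p = 8e-05; Spearman's rho 0.40, permutation p = 0.00029) and 0.39 in sarcomatoid samples (n = 52, permutation p = 0.0047, adjusted p = 0.0047; rho 0.34, permutation p = 0.015). Without the 2 samples farthest from the median, r was 0.45 and 0.24. With the global mean, r was -0.40 in conventional (permutation p = 0.00028) and -0.12 in sarcomatoid samples (permutation p = 0.39). Within set 3 alone the RNU48 values were 0.50 and 0.23, and within set 1 they were 0.08 and 0.48.

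By detection, 79 of the 377 human assays differed in the share of samples with Ct under 35, 73 detected less often and 6 more often in sarcomatoid samples (Fisher's exact test, Benjamini-Hochberg). Detection is not corrected for yield, and the always detected assays were 2.62 cycles later in sarcomatoid samples. A weak assay can thus be detected less often there without a change of its own. No detection test was run in matched samples. miR-874 was detected in 2 of 52 sarcomatoid samples (3.85%, exact 95% interval 0.469 to 13.2) and 64 of 80 conventional ones (80.0%, 69.6 to 88.1), and was detected less often within both sets. miR-346 went the other way, detected in 67.3% of sarcomatoid (52.9 to 79.7) and 20.0% of conventional samples (11.9 to 30.4), as did miR-202 and miR-672. Within sets, miR-202 differed in both, while miR-346 did not pass the threshold in set 3 (adjusted p = 0.20) nor miR-672 in set 1 (adjusted p = 0.25). miR-429 was detected in 41 of 52 sarcomatoid and in all 80 conventional samples. miR-874 and the shares were named after their values were seen. Within set 1 the count was 3 and within set 3 it was 29. The number of detected assays per sample was lower in sarcomatoid by -27.6 (permutation p = 1e-05), -25.9 within set 1 (exact permutation p = 0.032) and -22.7 within set 3 (permutation p = 0.0062).

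The control assays differed between the groups as well. RNU48 stood at Ct 18.2 ± 2.33 (SD, n = 80) in conventional and 21.2 ± 3.38 (SD, n = 52) in sarcomatoid samples, and RNU44 at 20.5 and 23.6 (both permutation adjusted p = 2e-05). U6 stood at 14.4 and 16.0 (adjusted p = 0.0083), a smaller gap than for RNU48, and without the samples with few detected assays the U6 difference was 0.60 (permutation p = 0.25). Within sets, RNU48 differed by 3.32 in set 1 (exact permutation p = 0.010) and 1.94 in set 3 (permutation p = 0.0029), RNU44 by 2.72 (exact permutation p = 0.080) and 2.05 (permutation p = 0.011), and U6 by 1.41 (exact permutation p = 0.36) and 1.71 (permutation p = 0.034). The plant assay ath-miR159a, which has no human target, did not differ (adjusted p = 0.72) and read 40 in 121 samples.

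**Figure D4:**
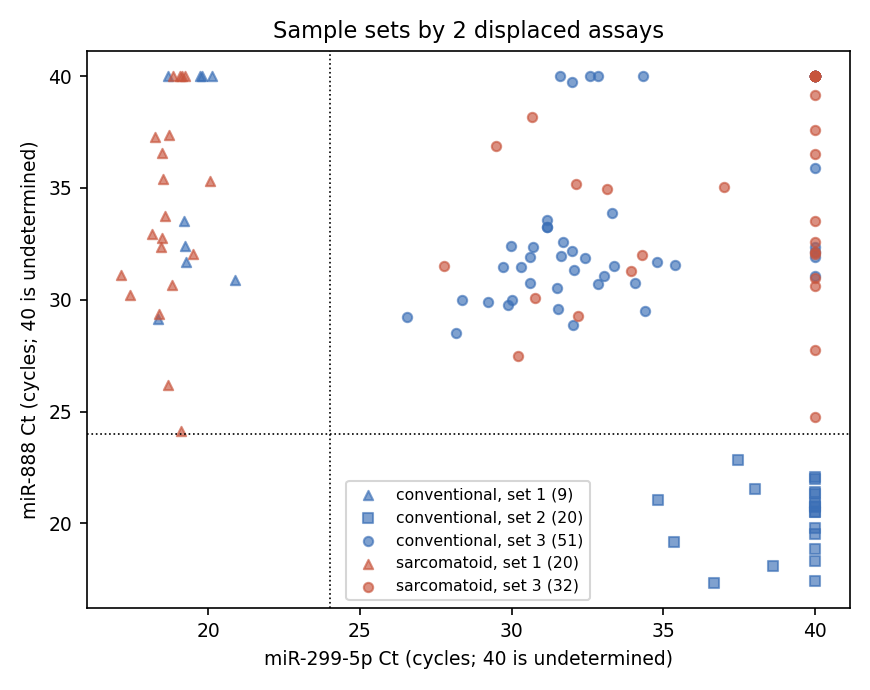
Ct of miR-299-5p against Ct of miR-888, both in cycles, for all 132 samples, with dotted lines at the limit of 24 that defines the sets. Set 1 holds 9 conventional and 20 sarcomatoid samples, set 2 holds 20 conventional samples, and set 3 holds the other 83.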

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

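The test of unequal differences between sets was chosen after the results were seen. So were the tests of the reference, the detection limit, the yield in the count of higher assays, the sample sets and the epithelial share. The splits within sets and the matching on mean Ct also came after. The counts of random splits over all 132 samples were set before.

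The difference between the diagnoses was unequal in sets 1 and 3 for 15 of 296 assays (limma, adjusted p under 0.05), 14 of them with the larger value in set 1, led by miR-193a-3p, which was called higher in set 1 (3.11) and lower in set 3 (-1.02). None of the 15 was a miR-200 family assay, and miR-202, miR-627 and miR-424 were among them. The median of set 1 minus set 3 over all 296 assays was 1.35, and RNU48 differed between the diagnoses by 3.32 cycles in set 1 and 1.94 in set 3. Of 100 splits of the diagnoses within the sets, 7 gave as many assays, so chance is not excluded for this count. The highest other split gave 58, and whether this reflects structure among the samples was not tested. Among all 132 samples, 1 of 100 splits, the real one, gave as many as 136 differing assays, and the highest other split gave 1. The same held for the 79 assays with a different detection share, again with 1 in the highest other split. Chance alone is thus unlikely for both counts, but these splits also break the link of diagnosis with sample set. In splits that kept the sets, again only 1 of 100, the real one, gave as many assays. The highest other split gave 97 without set in the fit, 57 with set as a covariate and 31 by detection. Chance is thus unlikely for these counts too, as far as 100 splits can show. For the lists chance is not excluded: 55 of 100 splits called at least 3 lists at the preset correlation, the highest other split calling 7. With an estimated correlation 6 of 100 splits called at least the 1 list that was called, the highest other split calling 2, so chance is not excluded for that count either. These splits count any called list and do not test the miR-200 family itself. Its mean differed by -5.16 log2 units (permutation p = 1e-05), by -3.45 within set 1 (exact permutation p = 0.044) and by -5.54 within set 3 (permutation p = 1e-05). These values argue against chance for the family mean.

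In conventional replicate 16, the plant control assay ath-miR159a read Ct 34.19, the only reading of this assay under 35. In the same sample 67 human assays lay within 0.01 cycles of a recurring reading of 34.19, against at most 4 human assays at any 1 reading in other samples. This sample had the most detected assays, 373. Without it, 110 assays were higher and 23 lower in sarcomatoid samples, in place of 113 and 23.

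The excess of higher over lower calls was weighed against 3 technical explanations. The share of higher calls was 83.1% with RNU48 and 19.3% with U6, which is consistent with the reference setting the balance. In samples matched on mean Ct, RNU48 was still 0.66 cycles later in sarcomatoid samples and U6 was -0.02 cycles apart. Readings set to the detection limit do not account for the whole excess, since 82.1% of the calls were higher among assays never at the limit. A lower RNA yield cannot be told apart from the diagnosis here, because the share was 61.1% with set and mean Ct as covariates but 80.2% in matched samples.

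The 3 sets of samples may reflect a technical batch of cards or runs. Across assays other than the 2 defining ones, the differences of set 1 from set 3 correlated with r = 0.51 between conventional and sarcomatoid samples, across assays that are not independent. RNA yield is argued against as the cause of set 1, since its mean Ct differed from set 3 by 0.473 cycles in conventional samples (95% interval -1.09 to 2.04) and 0.565 in sarcomatoid samples (-0.588 to 1.72), while the ranges of miR-299-5p lay 5.66 and 7.71 cycles apart, earlier in set 1. For set 2 the mean Ct was earlier by -2.45 cycles (-3.12 to -1.77), less than the 5.66 cycles between the ranges of miR-888, so yield is argued against as the whole cause there. In both diagnoses the title numbers of set 1 all lay below those of set 3, so the sets followed the numbering of the samples. The labels do not say what the numbering stands for and name no card lot. No biological explanation was tested.

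The lower miR-200 family was weighed against 3 explanations. Sample set is argued against as the whole cause, since the smallest difference with set as a covariate was -4.79. Lower yield is argued against as well, since in samples matched on mean Ct the median log2 difference of the family was -4.38 with RNU48. The index there differed by -4.60 cycles (permutation p = 1e-05), but a shift equal in all assays cancels in the index with or without matching. A lower share of epithelial cells cannot be told apart from the diagnosis: the smooth muscle and endothelial lists shifted apart by 0.81 cycles (permutation adjusted p = 0.0066), but the smooth muscle, fibroblast and leukocyte lists have members on both sides of 0, so no pair of lists decides. A change in the tumour cells themselves stays open as well and is a hypothesis only.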

How the results depend on the processing

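The set fits, the fits in matched samples, with mean Ct as a covariate, without conventional replicate 16, with its recurring reading as undetermined and with assays detected in every sample were chosen after the results were seen; the rest were planned. All values of the 5 miR-200 family assays under the alternatives were negative, from -6.96 to -3.11, and 4 were not past the threshold, each of them within set 1. The index ran from -6.17 to -4.60. Over all named assays and alternatives, 1912 values kept their side of the threshold, 105 passed it newly, 252 no longer passed it and 46 reversed. A reversal was counted only where the assay was called in the main fit or in the alternative. The 1912 thus include changes of sign in assays called in neither. The planned fit on deposited fold changes was not run. Readings near Ct 35 limit what can be compared for weakly detected assays. Unless stated, the cause of a change was not tested.

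Of the 136 differing assays, 113 higher and 23 lower, the global mean gave 53 lower, the median of detected assays 58 higher and 95 lower, U6 88 differing, 17 higher and 71 lower, and quantile normalization 60 lower. No detection filter gave 219 differing and 195 higher, from more assays tested. Array weights gave 42 lower, leaving out samples with few detected assays 40 lower, and the number of detected assays as a covariate 70 higher. Set 1 alone gave 78 differing, 74 higher and 4 lower, and set 3 alone 58 higher, both with fewer samples. Set with the global mean gave 57 lower, set with U6 49 differing and 18 higher, and set with mean Ct 69 higher and 44 lower. The 77 assays detected in every sample gave 28 differing, 23 higher and 5 lower, from fewer assays. The 3 called lists became 1 with an estimated correlation, 1 with set and an estimated correlation, 2 with the global mean (striated muscle adjusted p = 0.058), 2 with conventional titles under 45 (striated muscle adjusted p = 0.64), 4 in set 1, 4 with set and the global mean, 6 with set and mean Ct, and 5 in matched samples. The 79 assays with a different detection share became 44 without samples with few detected assays, 3 in set 1 and 29 in set 3.

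The U6 difference was 0.60 without samples with few detected assays and 1.41 in set 1, and that of RNU44 was 2.72 in set 1, none past the threshold. The difference in spread was 2.00 in set 1 and 0.91 in set 3, neither past it. The correlation of the family with the mesenchymal list was 0.084 in conventional samples of set 1 and 0.23 in sarcomatoid samples of set 3. With the global mean it reversed to -0.40 in conventional samples, -0.86 in set 1 and -0.39 in set 3, and to -0.12, -0.077 and -0.17 in sarcomatoid samples.

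With the median of detected assays, miR-152 reversed to -0.18, miR-19b to -0.024, miR-25 to -0.14, miR-29c to -0.91 and miR-21 to -0.055. With U6, miR-152 reversed to -0.62, miR-499 to -0.14, miR-146b to -0.42, miR-19b to -0.47, miR-25 to -0.58, miR-34a to -0.18, miR-215 to -0.15, miR-29c to -1.35, miR-424 to -0.071 and miR-21 to -0.50. After quantile normalization miR-499 was -0.048 and miR-486-3p -0.32. With undetermined readings kept at 40, and equally with the deposited delta-Ct, miR-499 was -0.75, miR-486-3p -0.27 and miR-129-3p -0.24. With high readings as missing miR-486-3p was -1.01, and with the number of detected assays as a covariate it was -0.082. With conventional titles of 45 and above miR-518b was 0.58, without set 2 it was 0.23, and in set 3 it was 0.032.

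In set 1 miR-143 was 0.23. In set 3 miR-215 was -0.11 and miR-29c -1.27. With set and the global mean, miR-215 was -0.28 and miR-29c -1.22. With set and U6, miR-486-3p was -0.21, miR-129-3p -0.15, miR-215 -0.50 and miR-518d -0.029. With set and mean Ct, miR-499 was -0.064, miR-486 -0.32, miR-486-3p -1.14, miR-129-3p -0.66, miR-215 -0.25, miR-518d -1.37 and miR-520b -0.63. In matched samples miR-486-3p was -0.43 and miR-518d -0.55.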

Other observations

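The tests on miR-205 and miR-203 and the counts on C19MC were chosen after the values were seen. The test of neighbouring genes was set before. Its fit with set as a covariate was not, since the sets were found after the main results.

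Sarcomatoid tumours lay on both sides of a gap in the miR-200 family, whose width was not tested. On the global mean scale, the widest gap in the middle of the 52 values was 1.26 log2 units wide around -2.47, with 17 samples above it (median -0.07) and 35 below (median -6.99). Of the 80 conventional samples, 74 lay above the same point, and the median of all 80 was 1.26. Both sides held both sets, with 8 of set 1 and 9 of set 3 above, and 12 and 23 below (Fisher's exact p = 0.54), and the mean Ct of always detected assays was 23.1 above and 22.2 below (permutation p = 0.13). These sides come from the data and are not groups of the study.

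Because of this gap, no correlation of miR-205 or miR-203 with the family over all sarcomatoid samples is given, although one was computed first. The correlation of the family with the mesenchymal list in the Results was taken over all 52 samples, from both sides of the gap. The hypothesis that miR-205 and miR-203 follow the family among sarcomatoid tumours was tested on each side, in 4 relations. Below the gap, r with the family was 0.505 for miR-205 (n = 35, permutation p = 0.0021, adjusted p = 0.0084; rho 0.49, permutation p = 0.0035) and 0.414 for miR-203 (permutation p = 0.013, adjusted p = 0.017; rho 0.47, permutation p = 0.0051). Without the 2 farthest samples r was 0.37 and 0.32. Above the gap, with 17 samples, r was -0.18 for miR-205 (permutation p = 0.49; rho -0.03, permutation p = 0.92) and 0.59 for miR-203 (permutation p = 0.013; rho 0.47, permutation p = 0.056). Below the gap, within sets 1 and 3, r was 0.60 and 0.51 for miR-205 and 0.67 and 0.29 for miR-203. Below the gap miR-205 and miR-203 thus varied with the family on the global mean scale, for a reason that was not tested. The values compared share the subtracted mean Ct and the limit of Ct 35, and both can raise r by themselves. In sarcomatoid replicates 30 and 33, miR-205 and miR-203 were both at the limit, at -10.5 and -10.4. No r with another reference is given, so a link between these microRNAs cannot be told apart from this. Single tumours departed from the relation in both directions. Sarcomatoid replicate 51 had the family at -6.16 and miR-205 at 4.53, and replicate 5, above the gap, had 1.22 and -8.79. No correlation of other single assays with the family is given for comparison.

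MicroRNA genes that neighbour each other changed more alike than random pairs. This hypothesis was tested on 200 pairs of assays whose genes lie at most 10 kb apart in assembly GRCh38.p14. The pairs use 105 assays, and a pair of genes recurs where 1 of them has more than 1 assay. Many of the pairs lie within the DLK1-DIO3 and C19MC clusters, so the mean leans on these loci, and no value without them is given. Of the 299 tested assays, 241 had a single gene by name. With set as a covariate, the mean absolute difference in log2 difference within a pair was 1.09, against 1.59 in 10000 random pairings, of which 0.08% were as low. Without the miR-200 family, the 196 other pairs gave 1.10 against 1.41, and 1.1% of random pairings were as low. MIR143 and MIR145 stood at -1.54 and -1.85, whereas MIR23B stood at -1.58 beside MIR27B at 0.33.

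The C19MC cluster was strongly read in a few conventional tumours. Within set 3, whose samples lack the displaced C19MC assays of set 2, the mean Ct of the 35 C19MC assays on the card reached 20.3 in a conventional sample, against a lowest value of 30.7 in sarcomatoid samples. Of 51 conventional samples, 10 lay below that value, and the medians were 32.6 and 33.3. These Ct values are not corrected for yield, and after subtracting the mean Ct of the always detected assays 4 lay below every sarcomatoid sample, with medians of 12.3 and 11.1, the conventional one being later. Up to 35 of the 35 assays were detected in a conventional sample and up to 27 in a sarcomatoid one.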
